A study of Mus musculus with 10 samples.

How the data were processed

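Transcription factor binding and histone H4 acetylation were measured by chromatin immunoprecipitation and sequencing in double mutant (Myod1 and Myf5) mouse embryonic fibroblasts carrying lentiviral MyoD, Myf5 or GFP. Per the labels' protocols, factor chromatin was crosslinked for 11 min and sonicated, while H4Ac chromatin was native and cut with 15 units of micrococcal nuclease for 18 min. Per the submitters' processing notes, CASAVA 1.8.2 and BWA 0.7.5 were used, and the builds mm9 and hg19 are named without a role. The peaks are mouse, since the lists hold 19 autosomes and the X chromosome. The last peak on chromosome 1 ends at 197068167, past the last GRCm38 gene of that chromosome, so positions were read as mm9 and never converted. The peak caller, the way in which the 2 replicates of each factor list were joined and the control used for the H4Ac lists are not given in the sources used here.

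Each deposited list gives position, width, maximum coverage, a coverage cutoff and a p-value per peak, with the same coverage and p-value for a control in the factor and H4Ac lists. The coverage (signal) is, per the file headers, the authors' maximum coverage in the peak, as whole numbers; the headers name no scaling to depth. The cutoff is the authors' coverage threshold for 1 of 5 bins of GC content. The p-value of each peak is the authors' own, per the file headers, and reached at most 9.52e-06 in the factor and H4Ac lists and 8.61e-08 in the mock lists. Some control p-values exceed 1 (up to 1.12), so they served only to find peaks with a control p-value of 1e-05 or lower. In the H4Ac list of cells with GFP, 1 control coverage held a placeholder and was treated as missing. Coverage was compared, ranked or filtered within a list only, and lists were compared by overlap.

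Samples were grouped by the antibody and transgene in their labels: 7 lists in 7 groups, and 3 input samples that entered no comparison. Peaks overlapped if they shared at least 1 bp. Gained H4Ac peaks overlap no peak of the cells with GFP, retained peaks overlap one, and lost peaks are GFP peaks that overlap none with the factor. Shares have exact binomial intervals at a confidence level of 0.95. Intervals of ratios of gained to lost or retained shares use a normal approximation of the log ratio. Those of GC-reweighted values and of the mock coverage ratio are percentiles of 100 bootstrap draws of peaks. Those of the gap between the MyoD and the Myf5 gain, with a coverage floor or in equal lists, use a normal approximation. For equal lists the whole-list gap was held fixed. Chance overlap is the mean of 100 random placements of the peaks within their chromosomes, from position 3000000 to the last peak end (20 placements for H4Ac at factor peaks). For the shared gain, placement was kept outside the GFP peaks, and lists from unchanged chromatin were simulated against a shared control list. Profiles count, in steps of 50 bp, the factor peaks whose position lies inside an H4Ac peak. The overlap step was tested on simulated lists of 40000 peaks with 3 planted overlap shares, which it recovered with an error of 0 percentage points.

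The comparisons, their tests, the rule for named positions and most alternatives were fixed before the data were examined. The rule names the 5 strongest peaks by coverage of each class: shared, in 1 factor list only, H4Ac gained with both, with MyoD only or with Myf5 only, and mock. Its parts on named genes and on 17 gene lists, and the intended counts of gene positions and E-box sequences, were not run, because the annotation used here is of another build (GRCm38) and no genome sequence was used here. Alternatives were a larger overlap, a distance of 500 bp, centres within 100 bp, the stronger part of each list, lists of equal length, removal of mock regions, and another random placement. Added after seeing the data were merged H4Ac regions, gained peaks with a coverage of at least 1.5 or 2 times their cutoff, and reweighting of gained, retained and lost peaks to the GC composition of the GFP list. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.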

Results

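Chromatin binding of the myogenic transcription factors MyoD and Myf5, and acetylation of histone H4, were mapped in mouse embryonic fibroblasts that lack both Myod1 and Myf5. The double mutant cells received MyoD, Myf5 or green fluorescent protein (GFP) from a lentivirus, were moved to differentiation medium 24 h after infection and were collected 20 h later. MyoD and Myf5 are basic helix-loop-helix proteins that direct cells to the skeletal muscle lineage, and acetylated histone H4 (H4Ac) marks active chromatin. The series asks whether the 2 factors have separate activities, so the comparisons were where each factor bound, where H4Ac was called with each factor, and how the 2 relate. Of 10 samples, 7 had a peak list: 1 each for MyoD, Myf5, H4Ac in each of the 3 cell populations, and mock precipitations with the MyoD and with the Myf5 antibody from cells carrying GFP. The other 3 were input DNA, for which no list was used here. Each group had 1 list, and the MyoD and Myf5 lists each covered 2 replicates together by their titles, so no replicate error could be computed and no p-value across replicates is given. Sequencing depth per sample is unknown from these files. Intervals of shares are exact (Clopper-Pearson) 95% binomial intervals. All intervals cover counting error only, and neighbouring peaks are not independent observations. Peak strength is the maximum read coverage that the authors gave for each peak, used within its own list. Positions are in the mouse build mm9.

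The MyoD list held 45015 peaks with a median width of 672 bp and a median maximum coverage of 49. The Myf5 list held 93787 peaks, 2.08 times as many, with a median width of 757 bp and a median maximum coverage of 55. MyoD peaks covered 33.1 Mb of the genome and Myf5 peaks 80.04 Mb. H4Ac peaks were narrower: 31120 peaks with a median width of 349 bp in cells with GFP, 36864 with a median width of 264 bp in cells with MyoD, and 32041 with a median width of 373 bp in cells with Myf5. The covered lengths were 13.0, 12.1 and 14.9 Mb, so the list from cells with MyoD had the most peaks and the shortest total length. Its coverage cutoffs were also the lowest, at 19 to 26 reads, against 21 to 30 with GFP and 20 to 31 with Myf5.

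The mock lists hold the peaks called with each antibody in cells without its target. The MyoD mock held 942 peaks and the Myf5 mock 1359. The authors' p-values reached 8.56e-06 in the MyoD list and 8.10e-06 in the Myf5 list, but at most 8.55e-08 and 8.61e-08 in the mocks, so the lengths of factor and mock lists do not rest on the same threshold. No MyoD peak overlapped a MyoD mock peak and no Myf5 peak overlapped a Myf5 mock peak. Control coverage in the factor lists stopped at 20 (MyoD) and 31 (Myf5), and the highest coverage cutoffs of the 2 mock lists were 20 and 32. The absent overlap is thus what leaving out sites called in the mock gives, and it does not measure background at the listed peaks. Mock peaks differed in kind from factor peaks: 18.7% (16.2 to 21.3) of the MyoD mock peaks and 15.5% (13.6 to 17.5) of the Myf5 mock peaks lay on the X chromosome, against 1.83% of MyoD peaks and 1.88% of Myf5 peaks. Of the MyoD mock peaks, 63.6% (60.4 to 66.7) overlapped a Myf5 mock peak. The strongest region of both mock lists was the same, on chromosome 2 at 98506243 to 98507641 in the MyoD mock (coverage 196368) and at 98506291 to 98507593 in the Myf5 mock (coverage 1314902). The next strongest in both was at 98502236 to 98503298 in the MyoD mock, with a coverage of 18834. Another lay on chromosome 6 at 103598894 to 103599439, with a coverage of 15384 in the MyoD mock and 92500 in the Myf5 mock. Others of the strongest mock peaks lay on chromosome 9 at 35112643 to 35113329 (MyoD mock coverage 16332), on the X chromosome at 139917397 to 139917801 (MyoD mock coverage 13892) and on chromosome 2 at 98505056 to 98505506 (Myf5 mock coverage 73508). Mock peaks made up little of the H4Ac lists: 35, 44 and 39 H4Ac peaks overlapped either mock in cells with GFP, MyoD and Myf5.

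MyoD and Myf5 bound largely the same places, and nearly the whole MyoD list was contained in the Myf5 list. Of the MyoD peaks, 97.5% (97.3 to 97.6) overlapped a Myf5 peak by at least 1 bp, 16.3 times the mean of 5.98% over 100 random placements of the peaks. In the other direction, 45.9% (45.6 to 46.2) of Myf5 peaks overlapped a MyoD peak, against 2.89% at random. These placements ran evenly along whole chromosomes, and none among a narrower set of regions was run for this overlap. The excess over random therefore does not allow for regions where peaks of any kind are more likely. How close the sites lay depended on the rule: the centres were within 100 bp for 56.0% of MyoD peaks and 26.9% of Myf5 peaks. Overlap of whole peaks left 1127 peaks in the MyoD list only and 50737 in the Myf5 list only. Peaks found in 1 list were weak within that list. Myf5 peaks without a MyoD peak had a median coverage of 39, against 111 for shared ones, and MyoD peaks without a Myf5 peak had a median of 32, against 50. With the Myf5 list split by strength into 10 classes of equal size, the share with a MyoD peak rose from 3.91% in the weakest class to 27.4% and 44.4% in the middle classes and 99.96% in the strongest. The MyoD list, split likewise, was matched throughout, from 90.6% in its weakest class to 99.8% in its strongest.

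**Figure D1:**
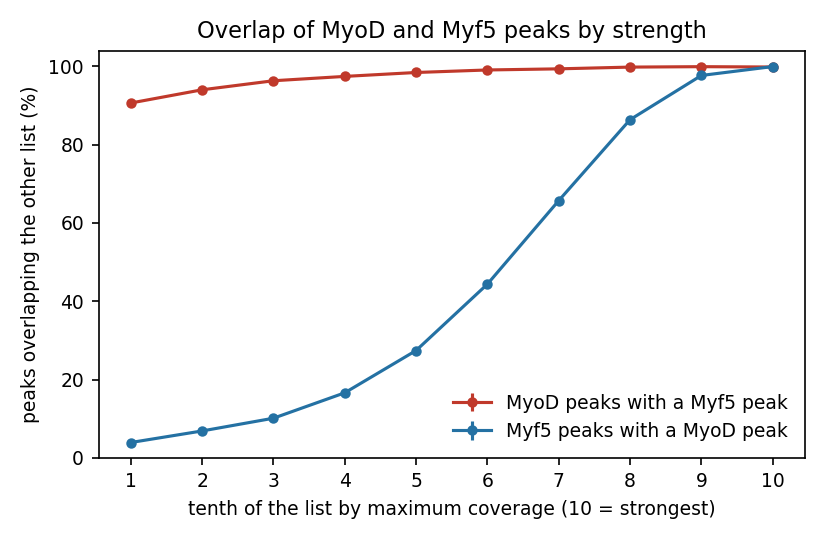
Share of MyoD peaks with a Myf5 peak (red) and of Myf5 peaks with a MyoD peak (blue), in percent, for 10 equal classes of the list by maximum coverage; bars are exact 95% binomial intervals. The Myf5 curve climbs from 3.91% to 99.96%, while the MyoD curve stays at 90.6% or above.

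Strength was also ordered alike at shared sites. Across 44305 overlapping pairs, the coverage ranks in the MyoD and Myf5 lists had a Spearman correlation of 0.792, given as a description across peaks, which are not independent replicates. With lists of equal length the overlap stayed high: 76.6% (73.8 to 79.2) of the 1000 strongest MyoD peaks overlapped one of the 1000 strongest Myf5 peaks. The share was 79.8% (78.6 to 80.9) for the strongest 5000, 81.3% (80.5 to 82.1) for the strongest 10000 and 82.9% (82.5 to 83.2) for the strongest 45015, against 0.142%, 0.508%, 0.964% and 3.25% at random. Of the 1000 strongest Myf5 peaks, 100% overlapped a MyoD peak of any strength, and of the 1000 strongest MyoD peaks 99.5% overlapped a Myf5 peak of any strength.

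The strongest shared MyoD peak lay on chromosome 1 at 88330973 to 88332744, with a MyoD coverage of 1678 and a Myf5 coverage of 1441. The next were on chromosome 12 at 113089460 to 113090968 (MyoD 1479, Myf5 3105), on chromosome 10 at 70755029 to 70755685 (1379 and 2287), on chromosome 13 at 37783596 to 37784674 (1358 and 3723) and on chromosome 1 at 172585401 to 172586528 (1217 and 2985). The chromosome 13 and 12 sites and the one at 172585401 on chromosome 1 were also among the 5 strongest of the Myf5 list, which further included sites on chromosome 19 at 46973176 to 46975081 (Myf5 2990, MyoD 892) and at 33142463 to 33143860 (Myf5 2800, MyoD 889). Of these 7 sites, the one at 88330973 on chromosome 1 had an H4Ac peak in all 3 cell populations. The sites on chromosome 12, chromosome 10 and chromosome 19 had an H4Ac peak in cells with MyoD only, and those on chromosome 13 and at 172585401 on chromosome 1 had none.

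A few strong peaks belonged to 1 list. The strongest MyoD peak of all, on chromosome 4 at 129504966 to 129506061 with a coverage of 2028, had no Myf5 peak. The next in this class lay on chromosome 2 at 127469167 to 127470245 (coverage 1470), chromosome 13 at 12955875 to 12958017 (992), chromosome 18 at 34163436 to 34164377 (730) and chromosome 2 at 166128781 to 166130042 (617). Each of these 5 overlapped a Myf5 mock peak, with mock coverages of 31 to 45, and the Myf5 list held no peak at any region of the Myf5 mock. Of all 1127 MyoD peaks without a Myf5 peak, 53 overlapped a Myf5 mock peak. The strongest Myf5 peak without a MyoD peak, on chromosome 12 at 86958874 to 86960279 (coverage 363), overlapped a MyoD mock peak in the same way. The next 4 Myf5 peaks of this class had coverages of 215 to 244 and no mock peak. They lay on chromosome 2 at 127871406 to 127872831, chromosome 6 at 100128273 to 100129176, chromosome 17 at 75452741 to 75453501 and chromosome 19 at 3823622 to 3825013.

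H4Ac was called in many of the same regions in the 3 cell populations, with gains and losses in both directions. In cells with MyoD, 11312 of 36864 H4Ac peaks overlapped none in cells with GFP (gained, 30.7%), and 7427 of the 31120 GFP peaks had no counterpart (lost, 23.9%). In cells with Myf5, 10211 of 32041 peaks were gained (31.9%) and 8476 GFP peaks were lost (27.2%). Gained and lost peaks sat near the calling cutoff: the median coverage was 1.14 times the cutoff for peaks gained with MyoD and 1.15 times for those gained with Myf5, against 1.59 and 1.63 times for retained peaks, those also called in cells with GFP. After merging the 3 lists, 18611 of 45627 regions (40.8%) were called in all 3 populations, 6388 in cells with MyoD only, 6265 with Myf5 only, 4792 with GFP only and 3786 with both factors but not with GFP. With each H4Ac list held to its 31120 strongest peaks, gains and losses with MyoD changed order, at 7700 gained and 8991 lost. Those with Myf5 did not, at 9417 and 8579. Lists of equal length differ in gains and losses only where a peak overlaps several of the other list, so this order says nothing of direction.

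Of the peaks gained with MyoD, 36.0% (35.1 to 36.9) overlapped a peak gained with Myf5, and 37.9% (36.9 to 38.8) of those gained with Myf5 overlapped one gained with MyoD. Random placement outside the GFP peaks gave 0.198% and 0.204%. Both gains are defined against the same GFP list, which raises their overlap without any effect of the factors. A simulation of 3 lists from unchanged chromatin, with noise set so that 74.5% of GFP regions were called again (73.7% observed), gave 39.4%, against 37.2% observed for merged regions. That noise was fitted to the observed lists and so includes any real change with the factors. The part of the shared gain due to the factors thus stays undetermined. Of merged regions called with MyoD and not with Myf5, 36.0% were also called with GFP. By this measure, cells with MyoD shared regions with cells with GFP nearly as often as with cells with Myf5.

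Ranked by H4Ac coverage in cells with MyoD, the 5 strongest regions gained with both factors each carried a peak of both. No ranking by H4Ac coverage in cells with Myf5 was made. The first lay on chromosome 4 at 59244362 to 59245006, with an H4Ac coverage of 148 with MyoD and 62 with Myf5, and factor coverages of 307 (MyoD) and 466 (Myf5). The others were on chromosome 17 at 48139102 to 48139489 (H4Ac coverage 123 with MyoD and 90 with Myf5), chromosome 5 at 77211124 to 77211821 (120 and 50), chromosome 16 at 93007191 to 93008134 (102 and 66) and chromosome 13 at 30749000 to 30749667 (98 and 79).

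Regions gained with MyoD lay at MyoD peaks more often than retained or lost regions did, and the difference widened with H4Ac strength. A MyoD peak overlapped 36.7% (35.9 to 37.6) of the gained peaks, 29.7% (29.1 to 30.3) of the retained ones and 16.2% (15.4 to 17.1) of the lost ones. Random placement of the gained peaks gave 1.79%. Among peaks with a coverage of at least 1.5 times their cutoff, the shares at MyoD peaks were 64.8% (62.1 to 67.5) of 1268 gained and 35.6% (34.8 to 36.4) of 14394 retained peaks. At 2 times the cutoff they were 87.2% (82.8 to 90.8) of 296 gained and 38.9% (37.8 to 39.9) of 8526 retained peaks. At Myf5 peaks the raw shares of the MyoD gain and of retained peaks differed only with such a floor. Random placement at the peaks' own widths gave 4.12% for gained and 4.76% for retained peaks. Relative to that, all gained and all retained peaks lay at Myf5 peaks 12.3 and 10.5 times as often. The shares there were 50.8% (49.8 to 51.7) of all gained and 50.1% (49.5 to 50.7) of all retained peaks, 951 of 1268 (72.5% to 77.4%) and 56.8% (56.0 to 57.6) at 1.5 times the cutoff, and 89.5% (85.5 to 92.8) and 60.5% (59.5 to 61.5) at 2 times.

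Cells with Myf5 did not show this pattern at the level of the whole list. A Myf5 peak overlapped 35.4% (34.5 to 36.3) of the peaks gained with Myf5, 50.2% (49.5 to 50.9) of the retained ones and 42.04% (40.98 to 43.1) of the lost ones. Reweighted to the GC composition of the GFP list, the shares were 41.1%, 50.3% and 41.3%. The gained share was 8.03 times that of random placement (4.41%), but 0.798 times that of placement among the union of all H4Ac regions, where the matching ratio for MyoD was 1.45. At 1.5 times the cutoff, 47.8% (44.7 to 50.99) of 991 gained and 53.9% (53.1 to 54.8) of 12788 retained peaks lay at a Myf5 peak. At 2 times the cutoff the shares were 61.2% (52.5 to 69.3) of 139 gained and 57.4% (56.3 to 58.5) of 7494 retained peaks, a difference within the counting intervals.

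**Figure D2:**
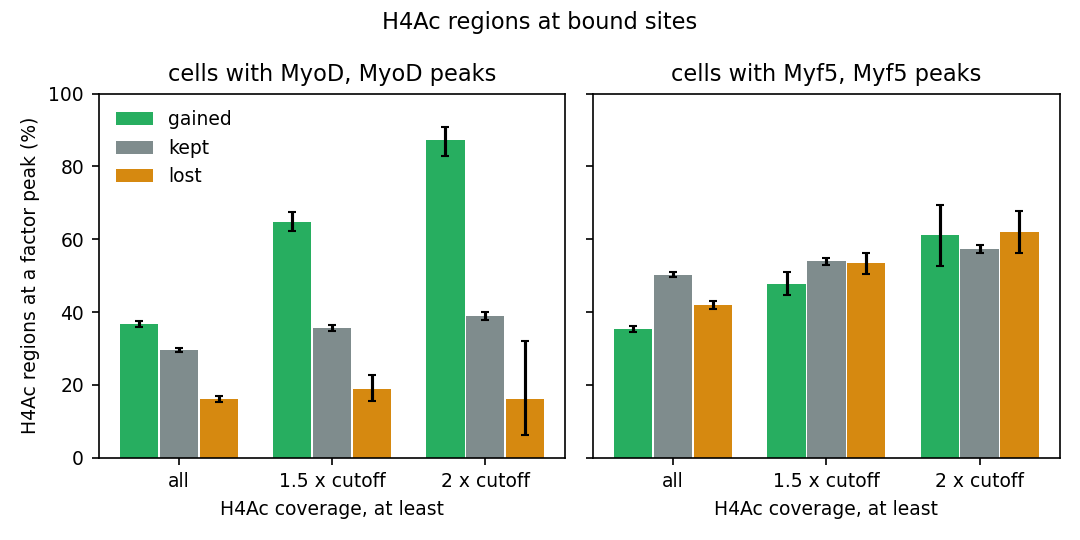
Share of H4Ac regions that were gained, retained (marked kept) or lost relative to cells with GFP and that overlapped a peak of the factor present, in percent, for all regions and for those with a coverage of at least 1.5 or 2 times their cutoff; bars are exact 95% binomial intervals. With MyoD the gained share rises from 36.7% to 87.2%, and with Myf5 the gained, retained and lost shares lie between 57.4% and 62.1% at 2 times the cutoff.

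Because the Myf5 list was longer, both gains were also set against the same MyoD peaks. At MyoD peaks lay 36.7% of the regions gained with MyoD and 21.9% (21.1 to 22.7) of those gained with Myf5, against 29.7% (29.1 to 30.4) of the peaks retained with Myf5. The Myf5 share also rose with H4Ac strength. At 1.5 times the cutoff it was 34.0% (31.1 to 37.1) of gained and 32.6% (31.8 to 33.4) of retained peaks. At 2 times the cutoff, 47.5% (39.0 to 56.1) of 139 gained peaks lay at a MyoD peak, 35.2% (34.1 to 36.3) of the retained and 37.6% (32.1 to 43.4) of the lost ones. In merged regions the share at a MyoD peak was 40.9% (39.7 to 42.2) for regions called with MyoD only and 13.9% (13.0 to 14.7) for those called with Myf5 only. It was 35.2% (33.7 to 36.7) for regions called with both factors and not with GFP, 32.3% (31.7 to 33.0) for regions called in all 3 populations and 17.8% (16.7 to 18.9) for those called with GFP only. Regions gained with Myf5 were also poorer in GC, with 32.9% in the bin of at most 40% GC, against 18.8% of regions gained with MyoD and 13.3% of the GFP list.

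**Figure D3:**
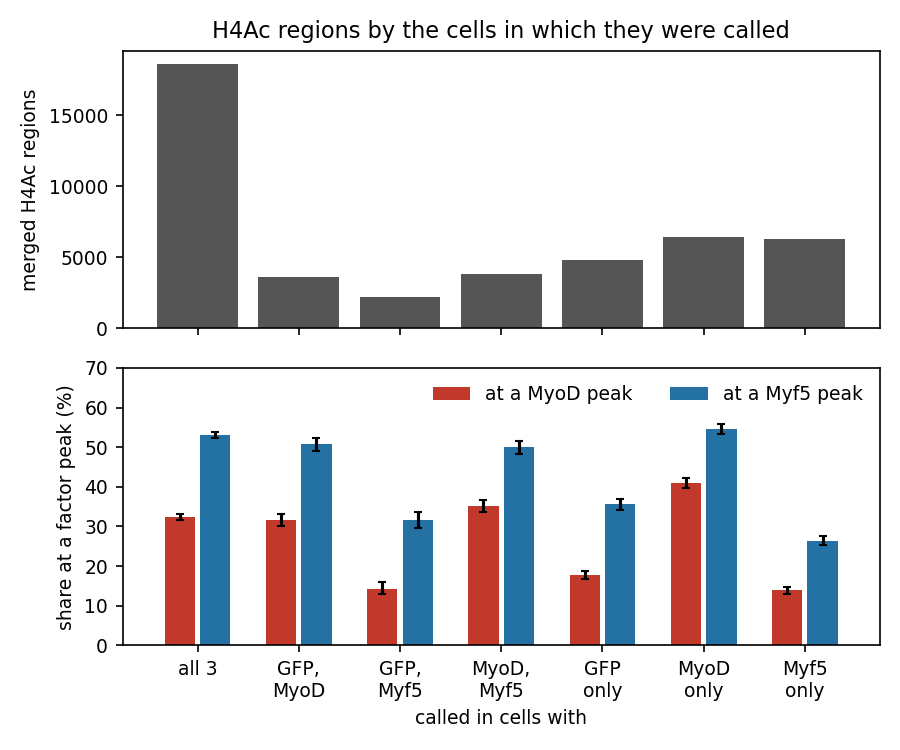
Number of merged H4Ac regions by the cell populations in which they were called (top) and the share of each class that overlapped a MyoD (red) or Myf5 (blue) peak, in percent (bottom); bars are exact 95% binomial intervals. Regions called with MyoD only have the highest share at a MyoD peak (40.9%), and those called with Myf5 only the lowest (13.9%), beside 14.3% for those called with GFP and Myf5.

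The strongest region gained with MyoD only lay on chromosome 7 at 53633753 to 53634390, with an H4Ac coverage of 93, a MyoD coverage of 169 and no Myf5 peak. Its control coverage was 16, against a median of 4 in that list, and is among the 18 of that list with a control p-value of 1e-05 or lower. Whether its reads came from the chromosome or from sequence carried by the virus was not tested, so its H4Ac and MyoD coverage cannot be assigned to the chromosomal site alone. The other 4 had control coverages of 2 to 6 and carried peaks of both factors. They lay on chromosome 6 at 30578428 to 30579368 (H4Ac coverage 91), chromosome 2 at 148558301 to 148558545 (82), chromosome 12 at 109907094 to 109907462 (67) and chromosome 12 at 113089666 to 113090067 (67). The last falls inside a shared factor site named above. Of the 5 strongest regions gained with Myf5 only, those on chromosome 10 at 69094296 to 69094916 (H4Ac coverage 63), chromosome 3 at 130412394 to 130412557 (61) and chromosome 14 at 32599376 to 32599983 (58) had no factor peak. The one on chromosome 2 at 45603761 to 45604008 (58) carried peaks of both factors (MyoD 348, Myf5 743), and the one on chromosome 12 at 55797568 to 55797769 (54) a Myf5 peak of coverage 51.

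Seen from the factor sites, most bound regions had no H4Ac peak, and the share that had one rose with MyoD at the stronger sites. Of all MyoD peaks, 14.4% (14.0 to 14.7) overlapped an H4Ac peak in cells with GFP, 18.6% (18.2 to 18.9) in cells with MyoD and 15.1% (14.7 to 15.4) in cells with Myf5, against 1.26% to 1.33% at random. With MyoD peaks split by strength into 3 classes of equal size, the shares were 11.5%, 12.3% and 11.4% in the weakest class, and 18.4%, 28.2% and 20.3% in the strongest. Among the 1000 strongest MyoD peaks they were 25.3% (22.6 to 28.1) with GFP, 50.1% (47.0 to 53.2) with MyoD and 31.7% (28.8 to 34.7) with Myf5. Among the 100 strongest they were 26%, 62% and 35%.

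**Figure D4:**
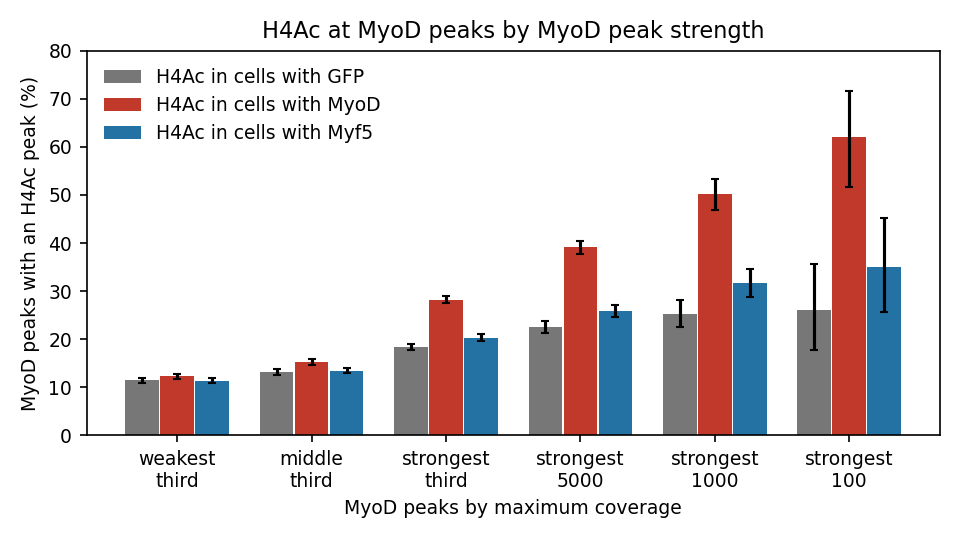
Share of MyoD peaks that overlapped an H4Ac peak in cells with GFP (grey), MyoD (red) or Myf5 (blue), in percent, by MyoD peak strength; bars are exact 95% binomial intervals. In the strongest 1000 the shares are 25.3%, 50.1% and 31.7%, while in the weakest class they lie between 11.4% and 12.3%.

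At Myf5 peaks the share with H4Ac was 11.6% (11.4 to 11.8) with GFP, 11.9% (11.7 to 12.1) with Myf5 and 13.6% (13.4 to 13.8) with MyoD. The 1000 strongest Myf5 peaks had shares of 18.9% (16.5 to 21.5), 25.6% (22.9 to 28.4) and 44.2% (41.1 to 47.3). So at the sites where Myf5 coverage was highest, H4Ac was called more often in cells with either factor than with GFP, and most often in cells with MyoD. Myf5 peaks without a MyoD peak had shares of 8.18% with GFP, 8.20% with MyoD and 8.27% with Myf5, which lie within each other's counting intervals. The same peaks were scored against each H4Ac list, and these intervals do not use that pairing. These peaks were mostly weak. The weakest of 3 equal classes of all Myf5 peaks had similar shares, at 8.32%, 8.20% and 8.28%. The absence of a MyoD peak was therefore not told apart from low Myf5 strength.

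Around the centres of the 5000 strongest MyoD peaks, H4Ac in cells with MyoD was highest on the flanks. H4Ac peaks covered 16.2% of the centres, 18.5% of positions 250 bp to the left and 19.3% of those 250 bp to the right, and 2.21% of positions at 1500 bp. In cells with GFP the centre was covered at 11.4% of sites and the flanks at up to 12.0%. In cells with Myf5 the centre was covered at 12.2% and the flanks at up to 13.9%.

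**Figure D5:**
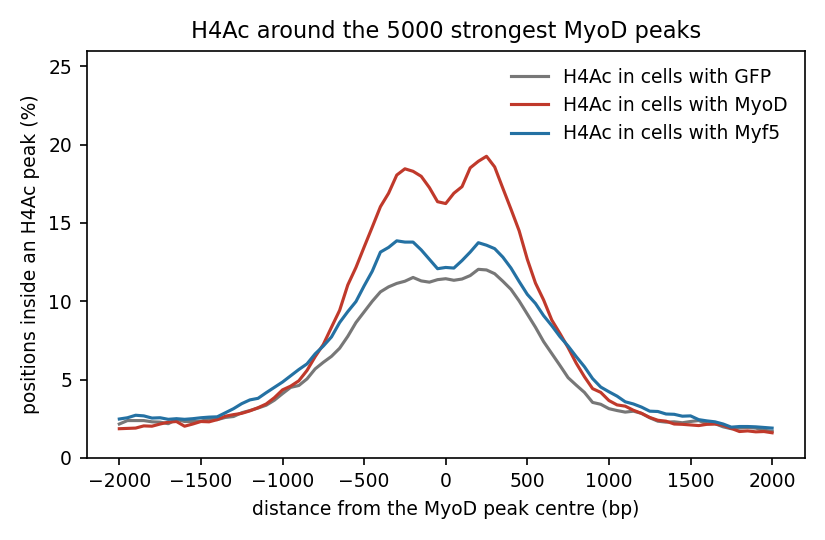
Share of the 5000 strongest MyoD peaks at which a position lies inside an H4Ac peak, in percent, by distance in bp from the MyoD peak centre, for H4Ac in cells with GFP (grey), MyoD (red) and Myf5 (blue). The MyoD line dips to 16.2% at the centre and reaches 19.3% at 250 bp.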

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

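Chosen only after the result was seen were the tests of GC composition, of weak calls and of list length for the gap between the MyoD and the Myf5 gain, and the GC reweighting and coverage floors for the other values. Over the whole lists, gained and retained H4Ac peaks differed in opposite directions with the 2 factors: the share of gained peaks at the factor's own peaks minus that of retained ones was 7.04 points with MyoD and -14.8 points with Myf5, and 8.28 and -9.17 points after reweighting gained and retained peaks to the GC composition of the GFP list. Among peaks with a coverage of at least 1.5 times their cutoff, the differences were 29.2 points with MyoD and -6.10 points with Myf5. At 2 times the cutoff they were 48.3 and 3.77 points. The latter rests on 139 peaks gained with Myf5 and lies within the counting intervals. With 1 list per group, the difference between the factors was not tested.

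For the MyoD gain, the tables argue against calls that come and go at the cutoff, since gained peaks lay at MyoD peaks 2.26 times as often as lost ones (2.14 to 2.40), where such calls would give under 1.2. At MyoD peaks they also argue against accessible chromatin that both assays favour as the whole cause. Gained peaks lay there 1.24 times as often as retained ones (1.1998 to 1.28), where it needs 1 or less. The ratio over all peaks stayed under the 1.5 set in advance as clear evidence against this explanation. It was 1.82 and 2.24 among peaks at 1.5 and 2 times the cutoff. Those floors were chosen after seeing the data, so they add no test of that bound. At Myf5 peaks it was 1.01, 1.32 and 1.48. These ratios do not allow for peak width. Over random placement at the peaks' own widths, the shares at MyoD peaks were 20.6 times for gained and 14.2 times for retained peaks. At Myf5 peaks they were 12.3 and 10.5 times. For the Myf5 gain at Myf5 peaks, the ratios were 0.842 to lost (0.812 to 0.873) and 0.705 to retained peaks, under the bounds of 1.2 and 1. After GC reweighting of all classes they were 0.996 (0.963 to 1.03) and 0.818 (0.794 to 0.838). Over random placement at the peaks' own widths, the shares were 8.03 times for gained, 9.39 for lost and 9.43 for retained peaks. Both explanations thus stay open for the Myf5 gain. Among the 139 peaks gained with Myf5 at 2 times the cutoff, the ratios to lost and retained peaks were 0.985 and 1.07 at Myf5 peaks. At MyoD peaks they were 1.26 and 1.35. Only the last, with 47.5% (39.0 to 56.1) against 35.2% (34.1 to 36.3), had intervals apart. It stayed under the 1.5 set in advance and came from a floor chosen after seeing the data, so no conclusion is drawn from it. Whether acetylation at MyoD sites responded to MyoD also stays open, since each cell population had a single H4Ac library.

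The gap between the gains at the same MyoD peaks was 14.9 points, and each test of it was chosen after it was seen. GC composition does not account for most of it, since 81.5% (77.6 to 85.8) stayed after reweighting both gains to the GFP list. Nor do weak calls, since the gap was 30.8 points (26.9 to 34.8) among gained peaks with a coverage of at least 1.5 times their cutoff, nor the greater number of H4Ac peaks in cells with MyoD, since 129% (119 to 138) of the gap stayed with the 31120 strongest peaks of each H4Ac list. A difference between the factors themselves, the amounts of the 2 proteins and variation between single H4Ac libraries stay open, and none of these was tested here.

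The Myf5 list was 2.08 times as long as the MyoD list. Background of the Myf5 antibody would raise mock coverage at the additional peaks, but its median at Myf5 peaks without a MyoD peak was 0.992 times that at shared peaks (0.982 to 1.01) within 20 classes of width, where over 1.1 was predicted; sites called in the mock were already missing from the list, so this speaks for weaker background only. Higher sensitivity of the Myf5 precipitation, by depth, antibody or protein amount, has the values it needs, since 99.96% of the strongest 10% of Myf5 peaks had a MyoD peak. Weak binding by Myf5 alone at many sites could give the same share, so the share does not tell it from higher sensitivity. Such binding stays open and was not tested.

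In the control columns of the H4Ac lists, which the comparisons did not use, 17 peaks with GFP, 18 with MyoD and 16 with Myf5 reached a control p-value of 1e-05 or lower.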

How the results depend on the processing

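With 1 list per group no replicate could be left out. No pairing of samples was possible because each group has 1 list, and peaks scored against several H4Ac lists were not analysed as pairs. Merged regions, coverage floors and GC reweighting were chosen after seeing the data. Of 71 alternative values that could move, 35 stayed within the counting interval of the main value (counts within 1.5 times), 35 moved beyond it and 1 reversed; for those that moved the cause was not tested beyond how each alternative is built. Another 14 could not move and say nothing of stability: 7 from leaving out unplaced sequences, of which the lists hold none, and the others where an alternative removed no peak behind the value or could only lower a count of 0. Removing peaks in either mock moved none of the values it could move. The gene-list, gene-position and E-box alternatives were not run. Unknown depth limits every list length and share.

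An overlap of 50% of the shorter peak gave a shared gain of 34.5%, and 31.5% (MyoD) and 30.1% (Myf5) of gained peaks at own sites. Peaks within 500 bp gave 97.7% of MyoD and 48.7% of Myf5 peaks shared, 11 and 15 factor peaks near their mocks, 4679 and 5439 lost H4Ac peaks with MyoD and Myf5, a shared gain of 43.4%, and 48.6% and 43.8% of the gains at own sites. The stronger 50% of each list gave 98.3% and 46.6% of factor peaks shared, 5219 and 4610 gained and 2910 and 3984 lost H4Ac peaks, fewer because less was listed, a shared gain of 43.0%, and 34.5% and 31.5% of the gains at own sites. At equal list length 82.9% of MyoD and 80.6% of Myf5 peaks were shared, and 24.0% of the Myf5 gain lay at Myf5 peaks. With H4Ac lists of equal length, 7700 peaks were gained and 8991 lost with MyoD, and 9417 gained and 8579 lost with Myf5. The order turned with MyoD although each count stayed within 1.5 times. Equal length itself brings gains and losses near balance, so this order says nothing of the direction of change. Centres within 100 bp gave 56.0% and 26.9% shared. Merged regions gave a shared gain of 37.2% and 38.8% of the MyoD gain at MyoD peaks. Coverage of at least 1.5 times the cutoff gave 64.8% and 47.8% of the gains at own sites, and 2 times gave 87.2% and 61.2%. GC reweighting gave 41.1% for Myf5. Placement among the union of H4Ac regions lowered the MyoD gain's excess from 20.6 to 1.45 times random, and turned that of Myf5 from 8.03 to 0.798. One-to-one pairs gave a rank correlation of 0.820, against 0.792.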

Other observations

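Gained H4Ac regions at bound sites were counted in windows of 100 kb. With MyoD, the 100 kb windows with the most such regions lay on chromosome 10 from 95700001 to 95800000 and on chromosome 9 from 116200001 to 116300000, each with 8 gained regions at a MyoD peak. The chromosome 10 window held 9 MyoD peaks, and 3 H4Ac peaks with GFP, 10 with MyoD and 4 with Myf5. With Myf5, the window with the most gained regions at a Myf5 peak, also 8, lay on chromosome 6 from 4400001 to 4500000. It was already rich in H4Ac, with 39 peaks with GFP, 40 with MyoD and 43 with Myf5. Another window, on chromosome 1 from 139800001 to 139900000 held 6 such regions, with 0 H4Ac peaks with GFP, 9 with MyoD and 8 with Myf5. These windows were chosen after their values were seen.

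The H4Ac peaks with the highest control coverage lay in the same place in all 3 lists, on chromosome 11 from 3052157 to 3065156 in cells with GFP. Control coverage there was 183 against an H4Ac coverage of 757, a ratio of 4.14.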
